A study of Mus musculus with 2 samples.

How the data were processed

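H3K9me3 was measured by ChIP-seq in embryonic mouse lung at day 14.5, per the labels, in 2 biological replicates that pooled 24 and 34 embryos of both sexes of strain B6NTac;B6NCrl/Lap and had fragments of 300 to 500 bp. The replicates are separate pools of embryos, with 2 technical replicates combined for replicate 1 and 3 for replicate 2, per the deposited file records. Peaks were deposited as 4 lists in the narrowPeak format on build mm10, per the file headers and the deposited records: 1 list per replicate, 1 called on both replicates together, and 1 named replicated that the records derive from other peak lists. The authors made each list from filtered alignments and 2 further files whose kind the records do not state, per those records. The aligner, the peak caller, its version and its threshold are not given in the sources used here.

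Each peak has an integer score, a fold enrichment (a ratio, in the signal column of the format), a −log10 p and a −log10 q, all deposited as the authors' caller gave them. The fold enrichment and −log10 values were used to describe, rank or filter peaks within a list, and the fold was also correlated between the replicate lists over overlapping peaks, as a description. The lists show a lowest −log10 p between 2.00 and 2.05, and only 4.75% of the peaks of replicate 1 and 25.5% of those of replicate 2 reached a −log10 q of 2, so both replicate lists hold many weak peaks. No read totals accompany the lists, so the depth of each sample is unknown and the longer list of replicate 2 cannot be set against its depth. A peak list also shows no signal below its threshold, so a gene without a peak is not a gene without the mark.

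The reference was the soft-masked GRCm38 assembly, with the GENCODE mouse release 21 annotation (Ensembl 96). Its chromosome names and lengths were checked against the mm10 positions of the peaks on chromosomes 1 to 19, X and Y. Peaks on contigs were not checked in this way. Sequence soft-masked in the reference stands for repeats, and the masking program is not given in the sources used here. Comparisons of replicates, genes, features and chromosomes used chromosomes 1 to 19, X and Y. Peaks on contigs entered the peak sets, the check of the replicated list against the other lists, the peaks named by fold and the account of contigs in the closing section. Peaks that overlap or touch were merged. A gene had a peak if at least 1 bp of its body lay under a peak, and the representative transcript of a gene gave its exons. A peak placed in an exon or intron has its summit there and may extend beyond it.

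The choices of tests, gene lists and naming rule were made before the data were examined, apart from the tests of first exons, of peaks that overlap both replicates, of windows without family genes and of overlap at a −log10 q of at least 2, and those of the closing section that are named there. Overlap of replicates was the share of peaks of a list that overlapped the other list by at least 1 bp, tested one-sided against 1000 rotations of replicate 1 along each chromosome with runs of at least 10 kb of N left out. Features were tested two-sided with the same rotations. Clustering was the share of bases in the top 1% of 1 Mb windows, against 1000 random placements within chromosomes. Gene lists were tested two-sided against 10000 random lists of protein-coding genes drawn from the same 20 bins of gene length, with Benjamini-Hochberg adjustment over 12 lists. The place of peaks within zinc finger genes was tested by rotating peaks within each gene. The difference from other genes is given without a p-value, because a permutation of gene labels, which was run, takes no account of gene structure. Random steps were seeded. Shares have exact Clopper-Pearson intervals at 95% and the count of 0 set beside the contig peaks was given the limit of 3 counts, and both cover counting error only.

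The gene lists were zinc finger genes by symbol, which includes members without a KRAB repressor domain, olfactory receptors, vomeronasal receptors, clustered protocadherins, Hox genes, ribosomal proteins, imprinted genes, germline genes, lung epithelium and mesenchyme, other lineages, pluripotency and trophoblast, and the H3K9 methylation machinery. Of all names asked for, 1 of the machinery list, Tasor, was not matched in the annotation. Genes were named by rule: up to 4 members of each list with the most bases under replicated peaks (up to 6 with any peak for lung and other lineages), the 10 protein-coding genes with the largest covered share among those with at least 2000 bases covered, the gene at or nearest to each of the 10 peaks of highest fold, and the genes in the 5 densest windows of 1 Mb. Zfp541 and the non-coding imprinted genes were added to these after their values were seen.

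Alternatives were the lists of single replicates and the pooled list, a −log10 p of at least 5, a −log10 q of at least 2, merging within 1000 bp, overlap by 50% of the shorter peak, equal numbers of top peaks, autosomes only, windows of 100 kb, promoters within 2500 bp of the start, at least 500 bases of gene body, and rotation in place of length matching. On simulated data, 19.7% of overlap was recovered where 20% had been planted. The zinc finger list was called in 100% of 20 runs with 60 of its genes given a peak. Random peaks led to 1 call in 220 tests of the 11 lists other than the protocadherins, which were called in 10 of 20 runs. These random peaks were placed singly, without the clustering of the real ones. The runs therefore do not give the rate of false calls for lists of neighbouring genes with clustered peaks. For the vomeronasal receptors, the SD of the count was 6.45 after rotation of the real peaks against 3.81 in length-matched lists. With 50% of the simulated peaks of zinc finger genes planted in the last exon and the others at random, the share there exceeded rotation by 35.6 percentage points. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Transposon classes were not analysed here, as no repeat annotation was used.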

Results

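Trimethylation of lysine 9 of histone H3 (H3K9me3), a mark of heterochromatin and of silenced repeats and genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in lung tissue of mouse embryos at day 14.5, when the airways branch. There was 1 group with 2 biological replicates, each a pool of embryos of both sexes, of 24 embryos in replicate 1 and 34 in replicate 2. Each replicate had its own peak list, and 2 further lists held peaks of the pooled replicates and the subset the authors call replicated. The design has no second condition, so the question for each result was where the mark lay and whether both replicates showed it there. Positions are on mouse build mm10, counted from 1. The lists carry no read totals, so the depth of each sample is not known here, and fold enrichments and −log10 p values of peaks are the authors' own. Intervals of shares of peaks or genes are exact (Clopper-Pearson) at 95% and cover counting error only.

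Peaks of H3K9me3 lay over zinc finger genes, clustered protocadherins, imprinted genes, germline genes and vomeronasal receptor genes more often than over other genes of the same length. In all, 2131 of 21938 protein-coding genes (9.71%) had a replicated peak over the gene body. In the lists of replicates 1 and 2 the counts were 4646 (21.18%) and 5606 (25.55%). Of the 429 zinc finger genes (symbols in Zfp, Zkscan or Zscan with a few relatives, many of them repressors of transposons that recruit this mark), 141 had a replicated peak, 4.27 times the 33.0 ± 5.16 (SD) of length-matched random lists. Of 34 imprinted genes, which are expressed from the allele of 1 parent, 27 had a peak against 4.74 ± 1.81, and of 40 germline genes 15 had a peak against 4.46 ± 1.91. The clustered protocadherins, cell adhesion proteins chosen by promoter in neurons, had peaks over 44 of 57 genes against 11.1 ± 2.69, and the vomeronasal receptors over 42 of 329 against 15.6 ± 3.81. These 5 lists passed with an adjusted p of 4.8e-04 (two-sided permutation test with 10000 random lists, Benjamini-Hochberg over 12 lists), the smallest that these lists can give. All 5 also passed when the peaks were rotated along their chromosomes in place of drawing genes, with an adjusted p of 0.006 for 4 of them and 0.0096 for the vomeronasal receptors. In the lists of single replicates the 5 ratios were lower, between 1.88 and 2.94, and each was past the threshold in both.

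**Figure D1:**
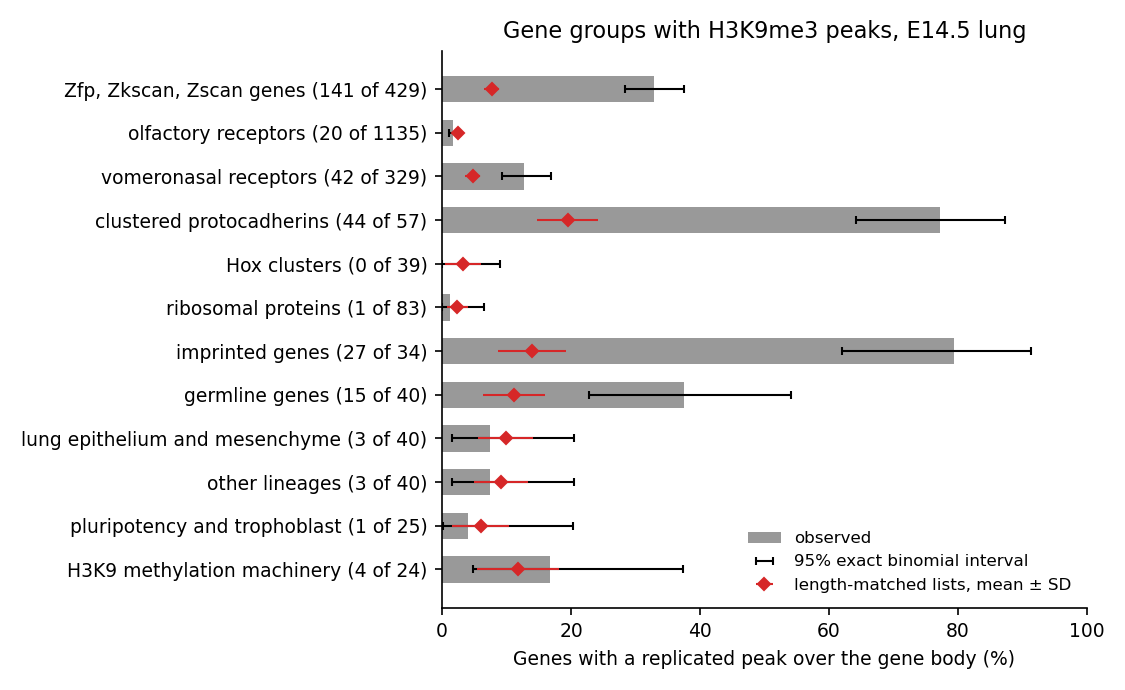
Percentage of the protein-coding members of each fixed gene list with a replicated H3K9me3 peak over the gene body (grey bars, with exact 95% intervals), and the mean and SD over 10000 random lists matched on gene length (red diamonds). The imprinted genes (79.4%) and clustered protocadherins (77.2%) have the longest bars, and the Hox genes are at 0.

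The zinc finger genes with the most bases under replicated peaks were Zfp981, Zfp873, Zfp110 and Zfp68. Zfp981 (chromosome 4, 146502027 to 146539395, plus strand) held 26 peaks that covered 13676 bases, 36.6% of its body. Zfp873 (chromosome 10, 82048123 to 82064745) had 12948 bases covered, 77.9% of the gene, with the summit of its strongest peak in the coding part of exon 4, its last. Zfp110 (chromosome 7, 12834761 to 12850577) was covered over 77.1% and Zfp68 (chromosome 5, 138603652 to 138619761, minus strand) over 72.3% of the gene body. The strongest peak of Zfp68, at 138604424 to 138607941 with a fold enrichment of 9.93, had its summit in the coding part of exon 6 of 6. In the other genes named, the strongest peak had its summit in an intron, intron 2 of Zfp981 (5 exons) and intron 4 of Zfp110 (8 exons). Coverage differed between the replicates, as the list of replicate 1 covered 8998 bases of Zfp981 and 8469 of Zfp68, and that of replicate 2 covered 16012 and 12473. The first exon of 1 zinc finger gene, Zfp541, carried a replicated peak against 2.11 ± 1.44 in length-matched lists (adjusted p = 1), while 17 had a peak within 2500 bp of the start against 7.13 ± 2.62 (adjusted p = 0.0072, permutation tests, Benjamini-Hochberg). First exons, here and below, were tested only after the data were seen.

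The imprinted genes with the most bases under replicated peaks were Gnas, Grb10, Kcnq1 and Mest. Gnas, which encodes a G protein subunit, had 10846 bases covered on chromosome 2, and its strongest peak spanned 6341 bp (174294474 to 174300814, fold 6.32) with the summit in exon 1 of the 12 exons of the representative transcript. In Grb10, a growth factor receptor adaptor on chromosome 11, the strongest peak had its summit in intron 1, at 12024797 to 12027566 with a fold of 7.43. Mest, on chromosome 6, had the summit of its strongest peak in intron 1, at 30736344 to 30739771 (fold 7.33), and Kcnq1, a potassium channel gene on chromosome 7, had it in intron 11 at 143295590 to 143295944 (fold 5.29). That peak of Kcnq1 also lay inside the non-coding gene Kcnq1ot1, which had 9 replicated peaks. Among the other non-coding imprinted genes, which the test left out, Airn had 9 peaks, Nespas 4, Meg3 3 and Peg13 3, while H19 had 0 in the replicated list and no base under the peaks of either replicate. Of the 34 protein-coding imprinted genes, 16 had a replicated peak over the first exon against 0.306 ± 0.542 in length-matched lists (adjusted p = 8e-04, permutation test, Benjamini-Hochberg).

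Germline genes act in germ cells or meiosis. Meioc (chromosome 11, 102663716 to 102682237) had 1 peak of 1065 bp that reached the first exon and had its summit in intron 1, with a fold of 4.65. Ddx4, a germ cell RNA helicase on chromosome 13, had 896 bases covered by 1 peak (112651580 to 112652606), which spanned the start of the gene on the minus strand. Stag3, a meiotic cohesin gene on chromosome 5, had an 870 bp peak (138280499 to 138281368, fold 5.02) with the summit in the 5-prime UTR, and Taf7l on chromosome X had 2 peaks, the stronger with its summit in intron 1 (134475403 to 134475738). Over the first exon, 10 of the 40 germline genes had a replicated peak against 0.23 ± 0.476 (adjusted p = 8e-04, permutation test, Benjamini-Hochberg). With a requirement of 500 bases under peaks, the ratio for germline genes was 2.59 and no longer past the threshold (adjusted p = 0.159, permutation test, Benjamini-Hochberg).

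The clustered protocadherins lie in 3 neighbouring groups on chromosome 18, and the peaks ran through the gamma group in particular. Pcdhga1 (37661793 to 37841873) had 85 replicated peaks over 77414 bases, 43.0% of its body, and Pcdhga2, Pcdhga3 and Pcdhgb1 had 75203, 72525 and 69014 bases covered, in large part the same bases because these genes share their 3-prime exons. The strongest peak, at 37762642 to 37763544 with a fold of 8.47, lay in intron 1 of all 4 genes. First exons are separate between members, and 40 of 57 carried a replicated peak against 0.712 ± 0.84 in length-matched lists and 0.594 ± 0.85 after rotation (adjusted p = 8e-04 and 0.008, permutation tests, Benjamini-Hochberg). On simulated random peaks the length-matched test of gene bodies called the protocadherins in 10 of 20 runs, so the rotated and first-exon values carry the comparison for this list.

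**Figure D2:**
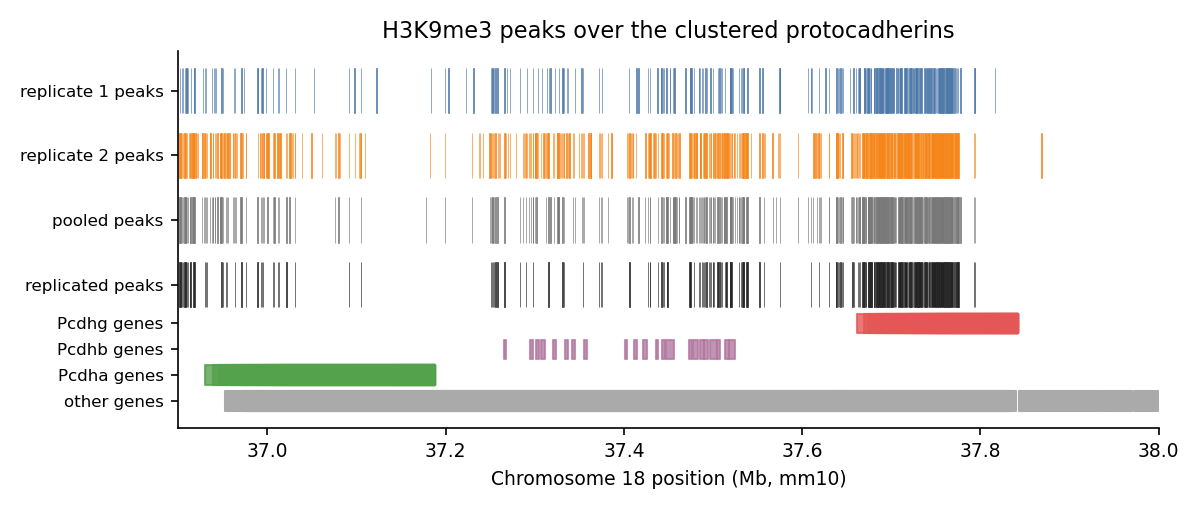
Map of the clustered protocadherin region of chromosome 18 (mm10 position in Mb), with the peaks of each replicate, the pooled list and the replicated list as bars above the bodies of the alpha, beta and gamma protocadherin genes and other genes. In the 1 Mb window from 37000001 the replicated list held 171 peaks, densest over the gamma group.

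Among the vomeronasal receptor genes, which are expressed in sensory neurons, Vmn2r60 on chromosome 7 had 2021 bases under 7 replicated peaks, 2.29% of its body, Vmn1r71 had 1275 bases, Vmn2r53 had 1272 and Vmn2r59 had 1049. Of the 1135 olfactory receptor genes, 20 had a replicated peak against 27.8 ± 4.90 (adjusted p = 0.247, permutation test, Benjamini-Hochberg), and the members with the most bases were Olfr867 with 623, Olfr398 with 481, Olfr943 with 443 and Olfr1347 with 394. The ratio for vomeronasal receptors lost its call within 2500 bp of the transcription start (1.81, adjusted p = 0.212) and over first exons (1.03, adjusted p = 1; permutation tests, Benjamini-Hochberg). The ratio for olfactory receptors depended on the list and rule, as it was above 1 in the lists of replicates 1 and 2, at 1.13 (adjusted p = 0.383) and 1.60 (adjusted p = 4e-04), and 0.0867 when 500 bases had to be covered (adjusted p = 9.6e-04, permutation tests, Benjamini-Hochberg). These values are from length-matched lists, which take no account of neighbouring genes, and rotation was not run for them. In the replicated list, rotation gave 28.9 ± 9.25 olfactory receptor genes with a peak, a wider spread than that of length-matched lists.

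The lists of lung development, other lineages, pluripotency, ribosomal proteins, Hox genes and H3K9 methylation machinery did not pass the test in either direction. Length-matched lists gave only 1.25 Hox genes, 1.49 pluripotency genes, 1.95 ribosomal protein genes and 2.83 machinery genes with a peak. With numbers so low the test could hardly have shown a lack of peaks for these genes, and the Hox count of 0 did not pass. Of 40 genes of lung development, Fgfr2, Foxp1 and Foxp2 had a replicated peak, 3 against 3.94 ± 1.72 in length-matched lists (adjusted p = 1, permutation test, Benjamini-Hochberg). Fgfr2, the receptor of the branching signal Fgf10, is annotated from 130162451 to 133123350 on chromosome 7 and its 6 peaks covered 0.076% of that span, with the strongest upstream of the representative transcript. Foxp1 had 415 bases covered in intron 5, and Foxp2 had 376 upstream of its representative transcript. Among 40 genes of other lineages, Syt1 had 928 bases covered, and Pax3 and Pax7, transcription factors of muscle progenitors, had 191 and 190 in intron 4 (3 genes against 3.66 ± 1.67, adjusted p = 1, permutation test, Benjamini-Hochberg). Of 25 pluripotency and trophoblast genes only Zfp42 had a replicated peak, of 535 bp in intron 1, and of 83 ribosomal protein genes only Rpl10l, which is also on the germline list (adjusted p = 1 for both lists, permutation test, Benjamini-Hochberg). Peaks of replicate 1 covered 0 bases of Rpl10l and those of replicate 2 covered 96. None of the 39 Hox genes had a replicated peak (exact interval of the share up to 9.03%), and of 24 genes of the H3K9 methylation machinery 4 did, namely Atf7ip with 2707 bases, Zfp445 with 1906, Morc2a with 646 and the methyltransferase gene Setdb1 with 247 (adjusted p = 0.928 for Hox and for machinery genes, permutation test, Benjamini-Hochberg). In the lists of replicates 1 and 2, genes with a peak numbered 6 and 10 for lung development, 10 and 11 for other lineages and 3 and 4 for Hox. They numbered 3 and 6 for pluripotency and trophoblast, 2 and 2 for ribosomal proteins and 8 and 7 for the machinery. None of these lists passed in either replicate.

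Within zinc finger genes the mark lay towards the 3-prime end, where the zinc finger domains are encoded. Of the 330688 bases under replicated peaks in the 141 zinc finger genes with a peak, 46.7% lay in the last exon, against 16.9% ± 2.10 (SD) when peaks were rotated within each gene, a ratio of 2.76 (p = 0.002, two-sided permutation test, the smallest its 1000 rotations can give). In 1921 other protein-coding genes with a peak and at least 2 exons, 3.55% of peak bases lay in the last exon against 2.73% ± 0.228 after rotation. Rotation within genes takes no account of sequence in which reads map poorly, and how far this raises either share over rotation was not tested. The difference between zinc finger and other genes was 43.1 percentage points, part of which comes with gene structure, since the rotated shares differ as well, and it is given without a p-value for that reason. Along the gene body of zinc finger genes, cut into 20 equal bins, the mean covered share was 0.169% ± 0.169 (SEM) in bin 1, 8.39% ± 1.91 in bin 10 and 31.9% ± 3.31 in bin 19. In the other genes it was between 2.43% and 3.77% in each bin. The difference was 41.1 points in the list of replicate 1 and 36.7 points in that of replicate 2.

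**Figure D3:**
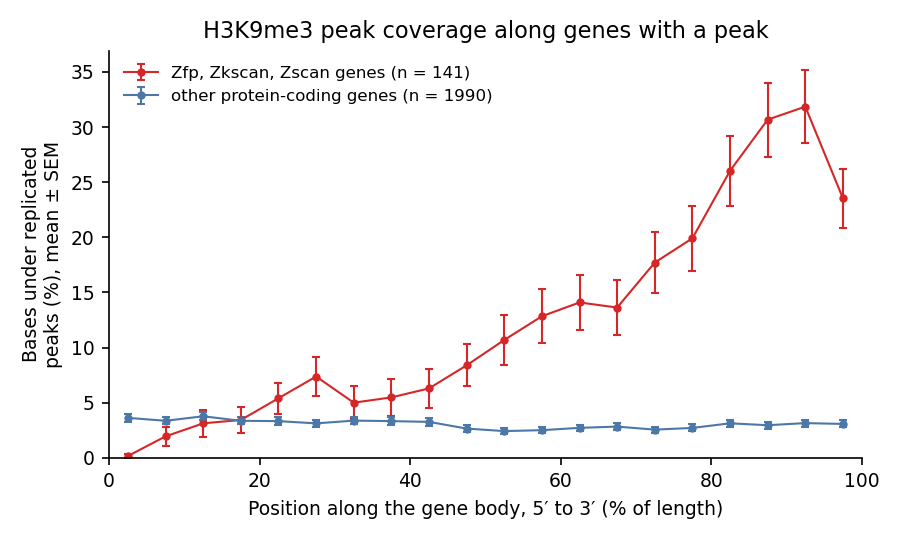
Mean percentage of bases under replicated H3K9me3 peaks in 20 bins along the gene body, from the 5-prime to the 3-prime end, for 141 zinc finger genes and 1990 other protein-coding genes with a replicated peak (error bars, SEM over genes). Coverage of the zinc finger genes is 0.169% in bin 1 and 31.9% in bin 19, and that of the other genes is between 2.43% and 3.77%.

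Replicated peaks were concentrated in few regions, and gene clusters filled the densest of them. The top 1% of 1 Mb windows, 28 of 2732, held 18.9% of all peak bases against 4.51% ± 0.133 (SD) when peaks were placed at random within their chromosomes (p = 0.001, one-sided permutation test, the smallest its 1000 placements can give). Each peak was placed on its own, although merging within 1000 bp left 8539 of the 10498 peaks. Regions called as several adjacent peaks thus raise the observed share over the placed one, and the p-value does not separate this from clustering of regions. In the lists of replicates 1 and 2 the share was 10.3% and 11.8%, with p = 0.001 in each (permutation tests). The densest window was chromosome 18 from 37000001 to 38000000, the protocadherin region, with 110882 bases, and 49 of its 67 protein-coding genes had a replicated peak. On chromosome 1, the window from 88000001 held 60556 bases over the Ugt1a genes, whose products glucuronidate bilirubin and drugs, and over Mroh2a, with a peak in 13 of 17 genes. The window from 82000001 on chromosome 10 had 54448 bases around Zfp873 and Zfp938, and that from 12000001 on chromosome 7 had 47467 bases, with peaks over 4 Vmn1r genes, Zfp606, Zfp329 and Zfp110 among others. On chromosome 4 the window from 147000001 held 42927 bases in 83 peaks, and 4 of its 17 protein-coding genes, Zfp982, Zfp979, Zfp984 and Zfp933, had a peak over the body. The peak lists of replicates 1 and 2 covered 87940 and 167016 bases of the protocadherin window and 38413 and 78249 of the chromosome 7 window.

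**Figure D4:**
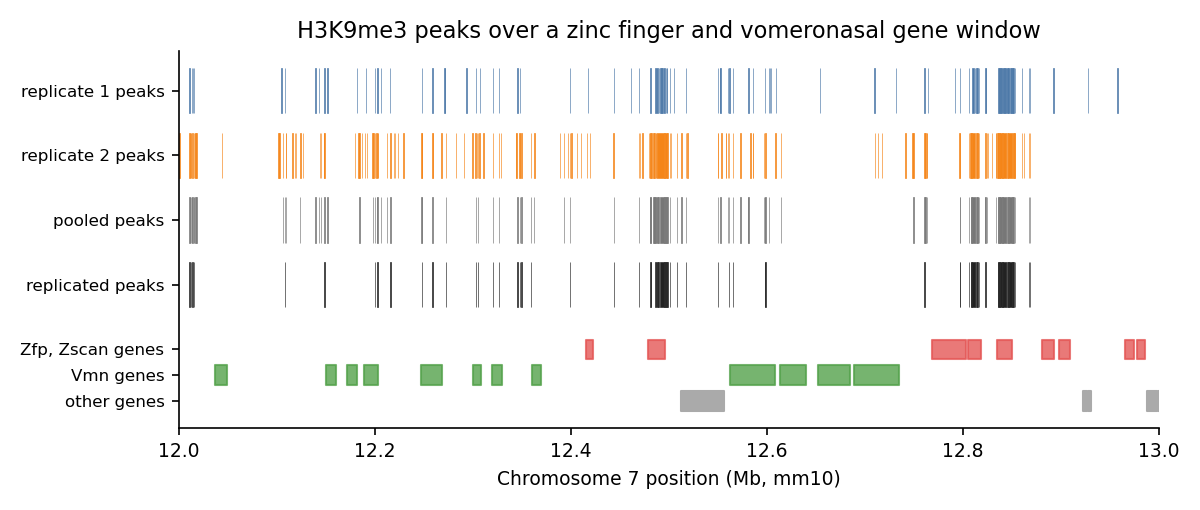
Map of chromosome 7 from 12 to 13 Mb (mm10), with the peaks of each replicate, the pooled list and the replicated list as bars above the bodies of zinc finger genes, vomeronasal receptor genes and other genes. The 72 replicated peaks of this window cover 47467 bases and are densest at zinc finger genes such as Zfp110.

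Some single genes were covered over most of their length. Among protein-coding genes with at least 2000 bases under replicated peaks, the gene model Gm21738 (chromosome 14, 19415857 to 19418930) was covered over 100% of its body by a peak of only 2.06-fold enrichment. Klf14, an intronless transcription factor gene on chromosome 6 (30956023 to 30959078), was covered over 94.3%, by a peak of 12.8-fold enrichment. Ugt1a1 on chromosome 1 (88211959 to 88218997) was covered over 93.0%, and its neighbour Mroh2a had 27413 bases under 17 peaks. Their strongest peaks had folds of 3.30 and 4.07 with −log10 p values of 18.1 and 22.1. The medians of replicated peaks on chromosomes were 3.38 and 5.65, so these −log10 p values were high for their folds. Asmt, which encodes the last enzyme of melatonin synthesis and lies on chromosome X (170672644 to 170678054), was covered over 89.1%, Il3ra on chromosome 14 over 78.1% and the single-exon gene Tmem185b on chromosome 1 over 72.4%. Zfp873, Zfp110 and Zfp68, described above, were the other genes of these 10.

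Of the 10 replicated peaks with the highest fold enrichment, 4 lay within genes, 3 between genes and 3 on contigs. The peak with the highest value, 15.5-fold, was at 12010278 to 12010995 on chromosome 7, in intergenic sequence 25757 bp from Vmn1r77. It was followed by the peak over Klf14 and by a peak of 11.1-fold on chromosome Y (259142 to 259472), for which the nearest protein-coding gene was Zfy1 at a distance of 465656 bp. A peak of 10.9-fold on chromosome X (170008987 to 170010208) lay within the gene model Gm21887, and the 3 peaks on contigs, whose genes were not examined, had 10.1-fold to 10.2-fold enrichment. The peak in Zfp68 came next, followed by peaks in intron 19 of 2210408I21Rik on chromosome 13 (9.71-fold) and 344152 bp from Olfr161 on chromosome 16 (9.03-fold).

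Exons and promoters held more of the replicated peak bases than rotated peaks did, and introns held less. Exons held 10.4% of the bases against 3.29% ± 0.276 (SD) after rotation, a ratio of 3.16 (2.08 and 1.70 in the lists of replicates 1 and 2), and promoters, from 1000 bp upstream to 100 bp downstream of a start, held 2.96% against 1.73% ± 0.167, a ratio of 1.71. The last exons of zinc finger genes alone held 154319 bases, beside 451910 in all exons outside promoters. Introns held 36.3% against 41.7% ± 1.67, and sequence soft-masked as repeats in the reference held 25.1% against 33.8% ± 0.674. Reads may map poorly in masked sequence, which rotation ignores, so its lower share does not show that the mark avoids repeats. The same limit holds for the exon, promoter and intron ratios, and how far mapping contributes to them was not tested. The GC content under peaks was 45.1% against 42.0% ± 0.239. Each of these 5 differences had p = 0.002, the smallest that 1000 rotations can give in a two-sided permutation test, over 6 features. Intergenic sequence held 50.3% against 53.3% ± 1.77 (p = 0.0859, permutation test), but in the lists of replicates 1 and 2 its ratio turned to 1.05 (p = 0.008) and 1.11 (p = 0.002, two-sided permutation tests), past the threshold in the other direction, so no direction is given for it. In the list of replicate 2 alone the promoter ratio was 1.10 (p = 0.06, two-sided permutation test).

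Chromosomes 7 and 17 had the highest density of bases under replicated peaks, and chromosomes X and Y the lowest. Chromosome 7 had 3280 bases under replicated peaks per Mb, 2.00 times the genome-wide value, and chromosome 17 had 1.91 times that value. Chromosome 18 was at 1.62, chromosome 4 at 1.36 and chromosome 14 at 0.581. Chromosome X, in pools of male and female embryos, had 333.5 bases per Mb, a ratio of 0.204, and chromosome Y had 61.1, a ratio of 0.0373 from 8 peaks. Of chromosome Y, 96.3% is soft-masked as repeats, in which reads may map poorly, so its low value does not show that the mark is rare there. Ratios in the lists of replicates 1 and 2 were 1.74 and 1.88 for chromosome 7, 0.241 and 0.319 for chromosome X, and 0.0187 and 0.0115 for chromosome Y. No test between chromosomes was made.

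**Figure D5:**
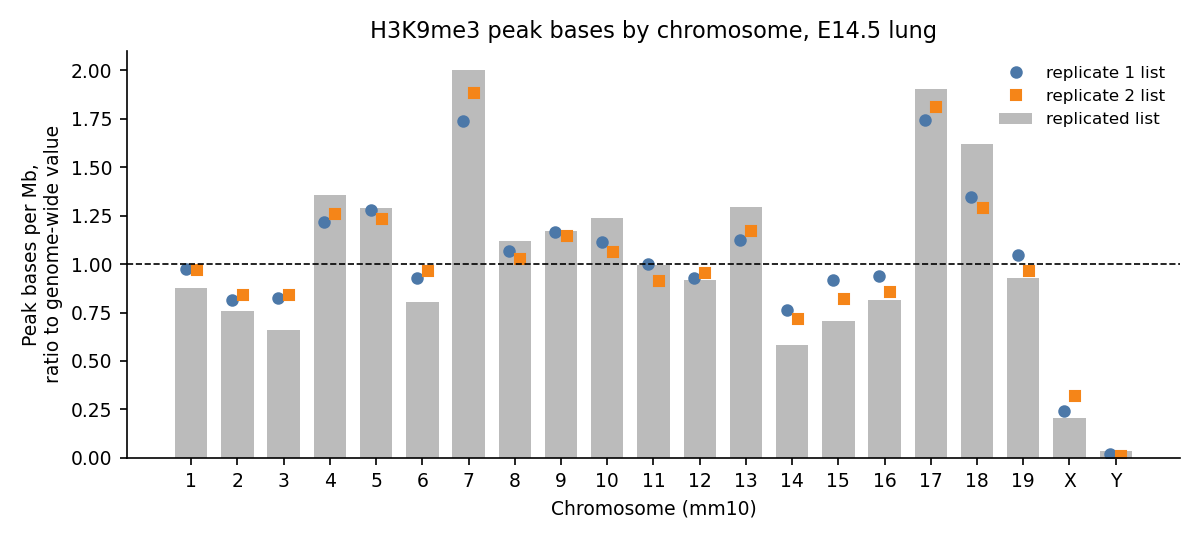
Bases under H3K9me3 peaks per Mb of each chromosome, as a ratio to the genome-wide value (dashed line at 1), for the replicated list (bars) and the lists of replicate 1 (circles) and replicate 2 (squares). Chromosome 7 stands at 2.00 and chromosome X at 0.204 in the replicated list.

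The replicates shared far more regions than rotated peaks did, but most peaks of each list were found in that list alone. Replicate 1 had 26873 peaks over 7.17 Mb and replicate 2 had 51775 over 15.1 Mb, 1.93 times as many peaks and 2.11 times as many bases. Of the peaks of replicate 1 on chromosomes 1 to 19, X and Y, 30.1% (8006 of 26613, interval 29.5 to 30.6) overlapped a peak of replicate 2 by at least 1 bp, against 1.17% ± 0.0829 (SD) after rotation. Of the peaks of replicate 2, 15.1% (interval 14.7 to 15.4) overlapped a peak of replicate 1 against 0.612% ± 0.0436, and the Jaccard index in bases was 0.0977 against 0.00203. Each had p = 0.001, the smallest that 1000 rotations can give in a one-sided permutation test. Peaks of replicate 1 at a q-value of 0.01 or below, 1277 in number, were found in replicate 2 peaks of the same threshold for 69.3% of those on chromosomes, a threshold added after the data were seen. In the other direction that share was 5.94%, and the Jaccard index at that threshold was 0.0809.

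Where the replicates overlapped, their fold enrichments went together loosely. Across 8006 overlapping pairs of peaks, which are not independent replicates, Pearson's r of log2 fold was 0.313 and Spearman's rho was 0.232, given without a test. Among 1702 pairs with a −log10 p of at least 5 in both lists the values were 0.486 and 0.346.

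The replicated list of 10498 peaks was a subset of the pooled list of 22557, since each of its peaks matched a pooled peak in position, fold and p. It covered 4.52 Mb, 0.164% of the ungapped genome, in peaks of a median width of 337 bp against 252 bp in the pooled list. Of its peaks, 66.8% (7011, interval 65.9 to 67.7) overlapped a peak of each replicate by at least 50% of the shorter peak, 3040 met this in replicate 2 alone, 428 in replicate 1 alone and 19 in neither. All 7011 pooled peaks that met it in both were in the replicated list. When only these peaks were counted, a choice made after the data were seen, the 5 gene lists named first passed again.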

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

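Both tests in this part were chosen only after the result was seen. The replicated list held 206 peaks on 19 contigs, which no comparison of genes or chromosomes used, while a count of 0 would allow 3. They made up 1.96% of replicated peaks but 6 of the 20 peaks with the highest −log10 p, and all 6 lay on 1 of the contigs. Over all 19 contigs the median −log10 p was 13.1 against 5.65 on chromosomes. A candidate explanation is sequence present in more copies than the assembly holds, which would raise the read number of sample and control alike: 84.2% of the contig peaks had a higher −log10 p than the median of chromosomal peaks whose fold was within 10% of theirs (171 of 203 compared). A higher enrichment of the mark on contigs stays open beside it, since 61.2% of the contig peaks had a fold above the median of chromosomal peaks, 3.73 against 3.38 at the median. No biological explanation was tested, because the design has 1 group.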

How the results depend on the processing

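Chosen only after the data were seen were the first-exon values, with and without rotation, the peaks that overlap both replicates, the windows without family genes, and the replicate overlap at a −log10 q of at least 2. Of 208 alternative values, 160 were counted as unchanged, most because they kept their direction and side of the threshold or stayed within their interval. The exceptions were 5 chromosome ratios within the SD of the replicates and 4 merged peak counts within a set factor. The 160 include all 15 for replicate overlap, all 5 for clustering and the ratio to rotation for the last exon of zinc finger genes in each alternative. Among those for replicate overlap, the Jaccard index does not use the rule of 50% of the shorter peak. Its value under that rule is the main one again and could not change. For overlap and clustering each p was the smallest possible, yet the shares moved. They were 22.9% to 69.3% for replicate 1 in replicate 2, 5.94% to 21.2% in reverse and 10.3% to 21.2% for clustering in 1 Mb windows. The cause of the changes below was not tested, except that a stricter threshold leaves fewer peaks by construction. The depth behind each list is unknown and limits every count of peaks.

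At a −log10 q of at least 2, the lists held 1277 (replicate 1), 13207 (replicate 2), 7032 (pooled) and 5753 peaks (replicated), and a single replicate in place of the replicated list gave 26873 to 51775. Merging within 1000 bp left 23926, 41000, 17732 and 8539 peaks in the same order of lists. With a −log10 p of at least 5, Pearson's r of log2 fold was 0.486, Spearman's rho 0.346 and the intergenic ratio 0.909, now past the threshold. Overlap by 1 bp put 67.8% of replicated peaks in both replicates.

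In the lists without replicate 1 or 2, the ratio to the genome was 1.74 to 1.88 for chromosome 7, 0.714 to 0.761 for chromosome 14, 1.75 to 1.81 for chromosome 17, 0.241 to 0.319 for chromosome X and 0.0115 to 0.0187 for chromosome Y. The pooled list gave 0.643 for chromosome 14 and 0.0234 for chromosome Y, and windows without family genes gave 1.48 for chromosome 7. The promoter ratio was 1.10 to 1.45, below the threshold in the list of replicate 2, and the intergenic ratio turned to 1.05 to 1.11, past the threshold in both, and to 1.01 in the pooled list, below it.

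The 5 lists that passed did so in each single replicate, in the pooled list, after rotation, at a −log10 p of at least 5 and with peaks that overlap both replicates. Among lists below the threshold, both single replicates turned the ratio for olfactory receptors, to 1.13 to 1.60 (past the threshold in replicate 2), and for other lineages, to 1.15 to 1.26. Only the list of replicate 2 turned it for Hox genes (range 0.919 to 1.03), pluripotency and trophoblast (0.846 to 1.40) and the H3K9 machinery (0.883 to 1.25). The pooled list turned it to 1.18 for olfactory receptors and 0.834 for the machinery. Within 2500 bp of the start, vomeronasal receptors were at 1.81, no longer past the threshold, and pluripotency genes at 2.01. With at least 500 bases covered, olfactory receptors were at 0.0867, now past it, germline genes at 2.59, no longer past it, and pluripotency genes at 1.52. Over first exons, zinc finger genes turned to 0.474 (0.772 with rotation), vomeronasal receptors were no longer past it at 1.03 (1.14), ribosomal proteins turned to 1.08 (4.57) and the machinery to 0 in both.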

Other observations

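The scan of gene families and the tests of unmasked and of family-free sequence on chromosome X were chosen only after results were seen. Outside the fixed lists, the families of genes with a shared symbol root and at least 10 members were tested for replicated peaks against length-matched lists. Of 240 families, 1 passed that test, the UDP-glucuronosyltransferases (Ugt). Of its 22 genes, 11 had a replicated peak against 2.81 (p = 2e-04, the smallest that 10000 lists can give, adjusted p = 0.048, two-sided permutation test, Benjamini-Hochberg), and against 2.84 after rotation of the peaks (p = 0.034, two-sided permutation test). These were 9 Ugt1a genes on chromosome 1, with Ugt2b34 and Ugt3a1. The 9 Ugt1a genes share their 3-prime exons and are thus 1 locus, and the first exon of 1 gene of the family carried a replicated peak. The length-matched test counted the 9 genes separately, which can make its p too small. The p after rotation was not adjusted over the 240 families, so neither p shows that the family stands out in the scan. The strongest peak of Ugt1a1 had a fold of 3.30 and a −log10 p of 18.1, which is high for its fold, as on the contigs. Whether extra copies of sequence contribute at this locus was not tested.

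The peaks with the highest −log10 p of the replicated list lay at a ribosomal RNA gene copy on chromosome 17, at 39843004 to 39846799 and 39847585 to 39848938, with values of 175.4 and 137.5 and folds of 4.12 and 3.50. On chromosome 11, peaks with a −log10 p of 64.9 to 103.9 and folds of 2.73 to 3.86 lay between 3184192 and 3200128 over Sfi1 and Drg1. The medians of replicated peaks on chromosomes were 5.65 for −log10 p and 3.38 for fold, so these values of −log10 p were high for their folds. Whether extra copies of sequence, as considered for the contigs, contribute at these places was not tested.

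Chromosome X had 0.187 times the peak bases per Mb of the autosomes in the replicated list. Repeats on X, of which 46.7% is soft-masked against 33.5% of the autosomes, do not account for this alone, since the ratio outside soft-masked sequence was at most 0.389 over the 4 lists, although masking is only a stand-in for sequence in which reads map poorly. A lack of zinc finger, receptor and protocadherin genes does not account for it alone either, as windows without such genes gave at most 0.338. Fewer copies of X in pools that include males remain open as a reason. Among peaks whose fold reached that of the highest 10% of autosomal peaks, the ratio was at most 0.372 (26 peaks on X in the replicated list, upper limit 0.546). Fewer copies could also lower the fold of peaks on X, so this ratio cannot decide it. A biological reason remains a hypothesis that may hold but was not tested, because the design has 1 group with both sexes in each pool.

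Most peaks of each replicate were absent from the other list, and 18178 peaks of replicate 1 and 40792 of replicate 2 overlapped neither the other replicate nor a replicated peak. Random positions under a lenient threshold do not account for all of them: 15.2% of those in replicate 1 and 23.9% of those in replicate 2 lay within 10 kb of a replicated peak, 2.40 and 3.77 times the share after rotation (p = 0.001, one-sided permutation test, the smallest that 1000 rotations can give). Weaker sites inside regions that hold replicated peaks may be part of them. The shares hold for 10 kb only, so the size of that part cannot be told and the origin of the rest stays open. These peaks also lay over 87 zinc finger genes in replicate 1 against 59.4 in length-matched lists, and over 188 against 78.7 in replicate 2 (p = 4e-04 and 2e-04, two-sided permutation tests).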
